A study of Homo sapiens with 7 samples.

How the data were processed

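Small RNA was sequenced from 7 captures made in A375, a human melanoma cell line. Per the labels' protocols, cells were harvested 24 h after seeding, crosslinked with 1% formaldehyde for 10 min and taken through miR-CATCHv2.0, in which an mRNA is pulled down with probes and the microRNAs bound to it are sequenced. The probes were directed at the 3' UTR of BRAF-X1, an isoform of the BRAF kinase mRNA. Groups were taken from the sample titles and descriptions: 3 captures with the ODD probe set, 3 with the EVEN probe set and 1 with scrambled probes. Per the series' design text the ODD and EVEN captures were independent captures. The descriptions also carry a number, called the description number here. It is 9 for replicate 1, 10 for replicate 2 and 12 for replicate 3 and for the scrambled library, and nothing in the labels says what it marks.

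The authors deposited RPM, reads scaled to a fixed library total, for 498 rows, each a hairpin and mature microRNA pair. Per the submitters' processing notes, CASAVA 1.8 and cutadapt 1.2.1 were used; the aligner, counting rule, microRNA annotation and genome build are not given in the sources used here. The unit RPM comes from the values, since each deposited column summed to 1e+06. Every value was a whole multiple of what 1 read is worth in its library, with a largest deviation of 1.6e-11 reads, so 100% of the values came out whole at a tolerance of 1e-06. The depths recovered this way, over all rows, were 4049 to 35508 reads. Of the 480 mature names, 17 had several hairpin rows, 35 in all. The reads of such rows were nearly equal for abundant names such as let-7a-5p (3807 to 3817 over its 3 rows), as if a read were counted at each hairpin, so the RPM total appears to hold repeats. They were unequal for miR-196a-5p (51 and 93), miR-7641 (18 and 35), miR-1285-3p (8 and 16) and miR-1-3p (2 and 6). The row with the most RPM stood for each mature name, a choice made after the table's layout was seen and before any test.

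Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPM + 10), with a mean for each of the 3 groups, eBayes with a trend and Benjamini-Hochberg adjustment at 0.05, two-sided. A microRNA was tested where it reached 10 RPM in at least 3 of the 7 libraries, which left 242. This filter cannot keep a microRNA seen in the scrambled library alone. Fold changes are on the log2(RPM + 10) scale. Because 1 read is worth more than the pseudocount in every library, the size of a difference that involves libraries with 0 reads is set by the pseudocount and can overstate the change. The scrambled group has 1 library, so its spread was assumed to be that of the other groups, with 4 residual degrees of freedom and a prior of 28.7. Standard errors and p-values against scrambled rest on that assumption and do not measure how a value of 0 reads varies. The contrasts were the mean of ODD and EVEN (called X1 probes) against scrambled, each probe set against scrambled, and ODD against EVEN. The 16 microRNA lists, the naming rule, the tests and most of the other settings were fixed before the data were examined. Of the lists, the 9 with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated one. MicroRNAs were named by a rule. Per comparison it took the 10 largest log2 changes in each direction among those that passed with all libraries on the same side. Places left over went to microRNAs of at least 100 RPM on average with the same-side condition, and the 10 most abundant and the 2 to 4 most abundant members of each list were added.

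Intervals of single values are exact Clopper-Pearson 95% intervals on reads, and the floor against a library with 0 reads is 3 reads per library, which is 646 RPM in the scrambled library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Calls expected with no difference were counted in 100 simulations that drew all 7 libraries from the pooled profile at their real depths. Distances between libraries are Bray-Curtis distances after thinning each library to 3046 reads, averaged over 50 thinnings. In chi-square tests every pair of libraries differed at an unadjusted p under 0.05. The closest were EVEN replicate 3 and scrambled, at p = 0.0233 by chi-square with no adjustment over pairs, which is near sampling noise. All were kept as separate samples.

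The fit was tested on simulated data with 40 of the 242 microRNAs changed in each of 20 draws. With as many raised as lowered, all under 5000 RPM, 24.5% of 4-fold and 41.0% of 8-fold changes were recovered for X1 probes against scrambled, with 5.55 false calls per draw on average. For ODD against EVEN the recovered shares were 29.0% and 42.0%, with 1.60 false calls. A first version raised all 40 at any abundance. It gave 29.05 and 44.15 false calls for the same comparisons, because the changed microRNAs took up part of the RPM total and moved every other value. These draws held counting error only and no further spread between captures.

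The alternatives were pseudocounts of 1 and 50, no filter, a filter of 100 RPM, median-of-ratios and quantile scaling, eBayes without the trend, each X1-probe library left out in turn, the description number as a block, and the X1-probe libraries with the scrambled library's number alone. Pseudocount 250, a mean of at least 1000 RPM, all hairpin rows, and ODD against EVEN without replicate 3 of each were chosen after seeing the data. Planned tests of edgeR on the recovered reads and of seed sites in the BRAF-X1 3' UTR were not run; the mature sequences and the transcript were not used here. Figures were drawn with matplotlib 3.10.9.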

Results

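The captures address which microRNAs bind the X1 isoform of BRAF in A375 melanoma cells. MicroRNA reads were measured in 3 ODD, 3 EVEN and 1 scrambled-probe capture. Counted over all hairpin rows, the depth was 10822, 35508 and 4049 reads for ODD replicates 1 to 3, 9292, 14492 and 4767 reads for EVEN replicates 1 to 3, and 4647 reads for the scrambled library. With 1 row per mature name the libraries held 3046 to 25679 reads, and the scrambled library 3479. A read was worth 28.2 RPM in the deepest library and 215 RPM in the scrambled one. Reads were found for 344 mature microRNAs in the deepest library, 183 in the scrambled library and 181 in EVEN replicate 3.

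The captured RNA was led by miR-92a-3p, a member of the miR-17-92 cluster, in all 7 libraries. It reached 147916 ± 10203 RPM with X1 probes (SD, n = 6) and 142673 RPM with scrambled probes. Next came let-7a-5p, of the let-7 tumour suppressor family, at 43498 ± 7692 RPM against 37659 RPM, and miR-92b-3p at 40027 ± 7654 RPM against 51216 RPM. miR-181a-5p, miR-191-5p, miR-423-5p, miR-21-5p, miR-100-5p, miR-27b-3p and miR-222-3p completed the 10 most abundant. Shares were taken over the 10 most abundant of each library, which need not be the 10 named. With ODD probes they held 41.0% ± 0.282 of the RPM total (SD, n = 3). The share was 41.9% ± 1.59 with EVEN probes (SD, n = 3) and 42.5% with scrambled probes. The 10 left out repeated hairpin rows, while the RPM total holds them. Without these rows the deepest library held 25679 of its 35508 reads. The difference between the groups was within the spread of the EVEN libraries.

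**Figure D1:**
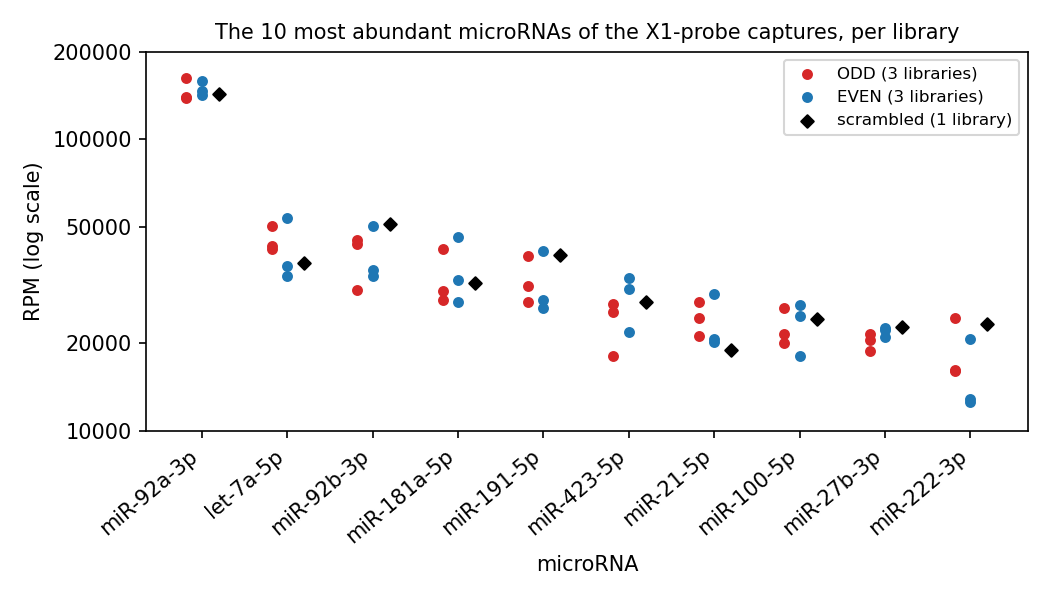
Level in RPM (log scale) of the 10 most abundant microRNAs of the X1-probe captures, with a point per library for ODD (3), EVEN (3) and scrambled (1) probes. The scrambled library lies close to the X1-probe libraries for miR-92a-3p, at 142673 RPM against a mean of 147916 RPM.

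The main question was which microRNAs were more abundant with X1 probes than with scrambled probes. miR-184, a microRNA known from cornea and lens, and miR-17-5p, of the miR-17-92 cluster, were higher. miR-184 had 6, 14 and 8 reads in ODD replicates 1 to 3, 7, 13 and 4 reads in EVEN replicates 1 to 3, and 0 in the scrambled library. Its level was 902 ± 558 RPM with X1 probes (SD, n = 6), 1.40-fold the scrambled library's floor of 3 reads (limma, log2 difference 6.33, SE 1.08, adjusted p = 0.000358, above 0 in 6 of 6 libraries and above the floor in 4). miR-17-5p had 50 reads in the X1-probe libraries and 0 in the scrambled one. Its level was 786 ± 393 RPM (SD, n = 6), 1.22-fold the floor of 3 reads (limma, log2 difference 6.16, SE 1.14, adjusted p = 0.000662, above 0 in 6 of 6 libraries and above the floor in 3).

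No tested microRNA was lower with X1 probes. With no filter 9 were, each with 0 reads in the X1-probe libraries and 1 to 3 in the scrambled one, such as miR-3661 with 3, named after its values were seen. By limma, 17 of the 242 microRNAs were higher and 4 lower at an unadjusted p under 0.05. Both calls rest on few reads: the mean X1-probe RPM predicts 4.19 scrambled reads for miR-184 and 3.65 for miR-17-5p, with a chance of 0.0151 and 0.0259 of drawing 0, and the pooled X1-probe reads predict 3.06 and 2.94, with a chance of 0.0468 and 0.0527. The exact 95% interval of 0 scrambled reads reaches 794 RPM, above the floor of 3 reads. The mean X1-probe RPM is 1.14-fold this limit for miR-184 and 0.991-fold for miR-17-5p, so no lower bound above 1 holds for miR-17-5p. The fitted log2 differences follow the pseudocount and ran from 2.09 to 9.63 for miR-184 and from 1.96 to 9.46 for miR-17-5p over the other settings. Simulated libraries with no difference, which held counting error only, gave 4.18 higher calls on average, at least as many as observed in 84 of 100 simulations. Both calls ended under the planned block on the description number and under pseudocount 250, chosen after seeing the data. Quantile scaling ended that of miR-17-5p.

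Of the microRNAs named by size that did not pass, miR-3180-5p, miR-181a-3p, miR-181c-5p, miR-98-5p and miR-769-5p each had 0 scrambled reads and an adjusted p of 0.310 by limma. miR-6772-5p, miR-421 and miR-128-3p also had 0 scrambled reads, with adjusted p of 0.395, 0.408 and 0.426. Their X1-probe means of 267 to 363 RPM were under the scrambled floor of 646 RPM, so no fold is given. miR-98-5p passed with no filter and without the eBayes trend (limma, adjusted p = 0.0316 and 0.0483, and 0.0916 to 0.695 over its remaining settings). In the other direction, miR-330-3p had 101 ± 155 RPM with X1 probes (SD, n = 6) and 1291 RPM, 6 reads, with scrambled probes (limma, log2 difference -5.08, adjusted p = 0.625). miR-1273a had 325 against 1506 RPM and miR-361-3p 240 against 1291 RPM, with adjusted p of 0.668 and 0.660 by limma. miR-27b-5p, miR-5684, miR-361-5p, miR-126-5p, miR-1290, miR-3195 and miR-15a-5p had 2 or 3 scrambled reads each and did not pass.

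None of the 10 most abundant microRNAs passed, and their 95% intervals bound the difference in RPM. RPM is a share of each library's total, so a difference in the total amount captured would not show in these intervals. The log2 difference was 0.049 (95% interval -0.48 to 0.58) for miR-92a-3p, 0.19 (-0.40 to 0.78) for let-7a-5p and -0.38 (-0.98 to 0.22) for miR-92b-3p. For miR-21-5p, a microRNA raised in many tumours, it was 0.32 (-0.29 to 0.93), and for miR-222-3p, known for its part in melanoma growth, -0.48 (-1.14 to 0.18). The differences of miR-181a-5p (0.070), miR-191-5p (-0.32), miR-423-5p (-0.11), miR-100-5p (-0.097) and miR-27b-3p (-0.11) did not pass. The sign of miR-181a-5p, miR-191-5p, miR-423-5p and miR-27b-3p turned under at least 1 other setting.

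**Figure D2:**
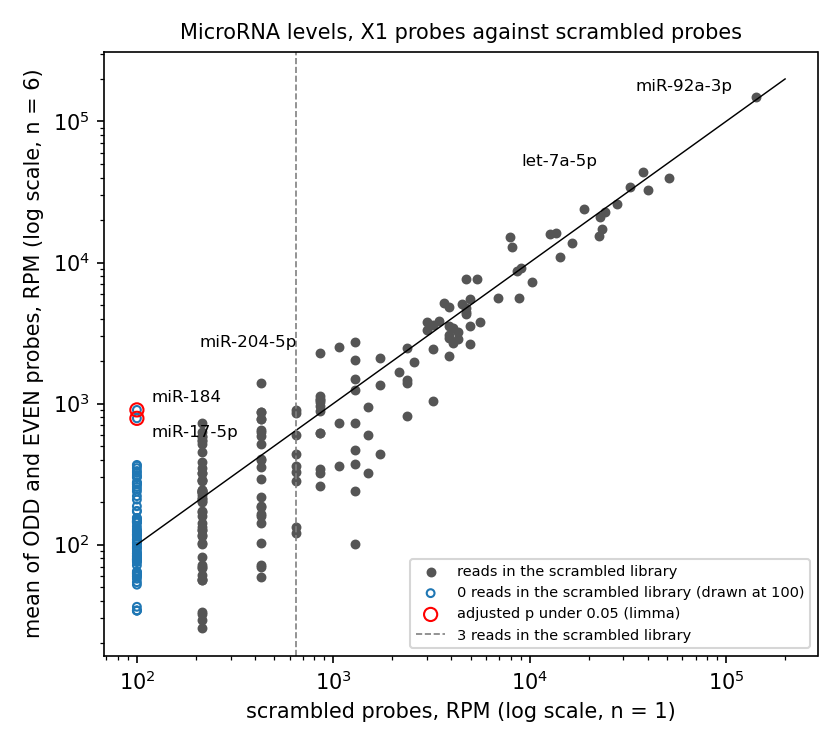
Mean RPM of the 6 X1-probe libraries (vertical, log scale) against RPM of the scrambled library (horizontal, log scale), with a point per tested microRNA, the line of equal level and a dashed line at the scrambled floor of 646 RPM. Open blue points had 0 scrambled reads and are drawn at 100 RPM; miR-184 and miR-17-5p, ringed in red, are the highest of them at 902 and 786 RPM.

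By list, 1 of the 6 tested members of the miR-17-92 and paralogous clusters rose, miR-17-5p, over all microRNAs and also adjusted over the list alone. Its relatives miR-92a-3p, miR-25-3p (5203 against 3658 RPM) and miR-93-5p (878 against 430 RPM) did not pass. Among the 9 lists tested with camera, this one had the lowest p, 0.0170 (adjusted p = 0.153, and adjusted p = 0.626 with an estimated correlation), and none passed. Of the let-7 family, 0 of 9 members passed over all microRNAs and 0 adjusted over the list alone; let-7f-5p had 15202 against 7962 RPM, let-7i-5p 12869 against 8177 RPM and let-7e-5p 4878 against 3873 RPM. Of the miR-181 family, 0 of 4 members passed over all microRNAs and 1 adjusted over the list alone, miR-181c-5p (adjusted p = 0.0457 by limma, 25 reads with X1 probes and 0 with scrambled). The pooled X1-probe reads predict 1.47 scrambled reads for miR-181c-5p, with a chance of 0.229 of drawing 0, so sampling alone could give its 0. miR-181b-5p had 16250 against 13557 RPM.

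miR-204-5p, a microRNA made in pigment cells from an intron of TRPM3, was the tested member of a list that also held miR-211-5p. It had 2286 ± 517 RPM with X1 probes (SD, n = 6) and 861 RPM, 4 reads, with scrambled probes. The log2 difference was 1.36 (limma, 95% interval 0.35 to 2.38, higher in 6 of 6 libraries), with an adjusted p of 0.310 over all microRNAs and 0.0101 adjusted over the list alone, which then holds 1 test.

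No member passed, over all microRNAs or adjusted over the list alone, in the miR-15/16 family (3 tested), the miR-23/27/24 clusters (5), the miR-30 family (5), the cluster of miR-221 and miR-222 (4), the miR-29 family (1), the X-linked clusters that start with miR-506 and miR-424 (1 each) and the DLK1-DIO3 cluster (1). miR-16-5p had 5529 against 4949 RPM, miR-27a-3p 2035 against 1291 RPM, miR-30a-5p 13798 against 16355 RPM, miR-30d-5p 8669 against 8608 RPM, and miR-221-3p 9132 against 9038 RPM. Entries that overlap rRNA, tRNA or other structural RNA had 0 of 18 members passing, with miR-1246 at 5647 against 6886 RPM and miR-619-5p at 3855 against 3443 RPM. For the miR-15/16 and miR-23/27/24 lists and the structural RNA entries, camera's direction was lower while the median and mean differences were above 0. The direction from camera compares members with the other tested microRNAs, so lower here means lower than the rest. For the miR-221 and miR-222 cluster the median (-0.25) and the mean (0.081) had opposite signs.

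No marker of another cell type passed over all microRNAs. The blood cell microRNA miR-486-5p had 22 reads in the X1-probe libraries and 1 in the scrambled one. The epithelial miR-141-3p and miR-200b-3p had 6 and 7 X1-probe reads and 0 scrambled reads. The neuronal miR-9-5p had 372 ± 145 RPM with X1 probes (SD, n = 6) and 1291 RPM, 6 reads, with scrambled probes, and the muscle miR-133a-3p 282 ± 230 RPM (SD, n = 6) and 646 RPM, 3 reads.

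Each probe set was also set against the scrambled library by itself. miR-184 and miR-17-5p passed with both, and these 2 were the higher calls of each set. No microRNA was higher with both under quantile scaling, without the eBayes trend or with the description number as a block, all planned. The same held under pseudocount 250 and a mean of at least 1000 RPM, chosen after seeing the data. With ODD probes the log2 differences were 6.26 for miR-184 and 6.27 for miR-17-5p (limma, adjusted p = 0.00128 and 0.00144), and with EVEN probes 6.39 and 6.06 (limma, adjusted p = 0.000929 and 0.00238). No tested microRNA was lower with either set, with 4 and 5 lower at an unadjusted p under 0.05 by limma for ODD and EVEN. Both comparisons use the same scrambled library, and 100 simulations with no difference gave an overlap of 2.63 on average, against 2 observed and 0.0165 for independent lists. Across microRNAs, which are not independent replicates, the differences of the probe sets had a covariance of 3.88 against 3.74 simulated, and a correlation of 0.819 against 0.831 simulated. The scrambled library cannot be split, so part or all of this overlap may come from sharing it.

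The ODD and EVEN probes target the same transcript, and their captures were compared with each other. let-7f-5p was lower with ODD probes, at 9581 ± 3759 RPM (SD, n = 3), than with EVEN probes, at 20823 ± 5153 RPM (SD, n = 3), and all 3 ODD libraries lay below all 3 EVEN libraries. The log2 difference was -1.16 (limma, SE 0.26, 95% interval -1.69 to -0.63, adjusted p = 0.0242). The scrambled library had 7962 RPM of let-7f-5p (37 reads, exact 95% interval 5612 to 10958). let-7a-5p, whose mature sequence differs from that of let-7f-5p by a single base, had 45390 ± 4620 RPM with ODD and 41606 ± 10762 RPM with EVEN probes (SD, n = 3 each, exact two-sided permutation p = 0.6). The same permutation test gave p = 0.1 for let-7f-5p, the smallest possible with 3 against 3.

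let-7f-5p was the only call of limma among 242 microRNAs, with 5 higher and 6 lower with ODD probes at an unadjusted p under 0.05. It passed in 8 of 18 other settings, and its log2 difference stayed between -1.46 and -0.96 in all 18, with adjusted p from 0.000869 to 0.939. Leaving out ODD replicate 1, ODD replicate 3 or EVEN replicate 2 ended the call by limma (adjusted p = 0.431, 0.232 and 0.0577).

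**Figure D3:**
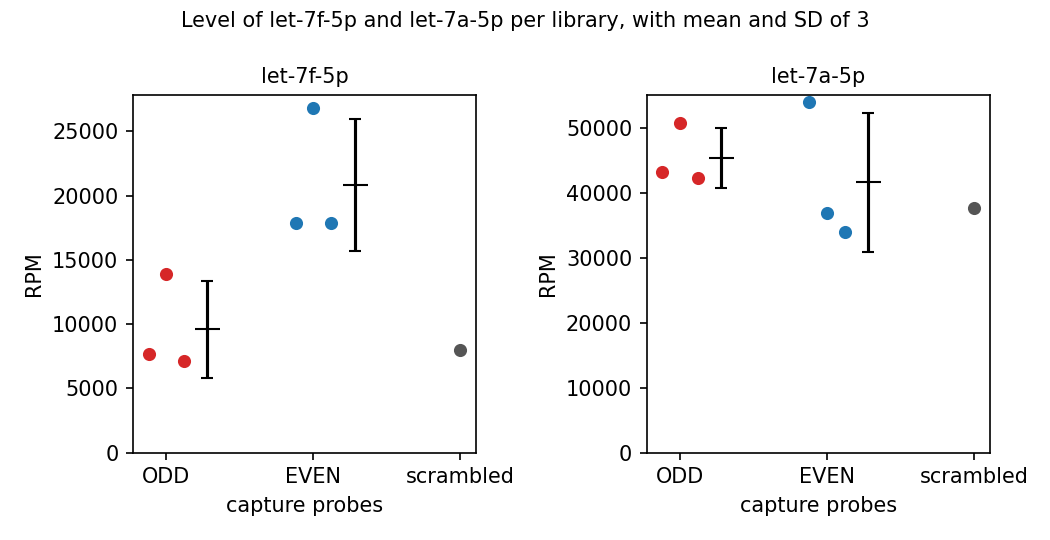
Level of let-7f-5p (left) and let-7a-5p (right) in RPM, with a point per library for ODD (3), EVEN (3) and scrambled (1) probes and the mean ± SD beside the groups of 3. The ODD libraries lie below the EVEN libraries for let-7f-5p, with means of 9581 and 20823 RPM, and overlap for let-7a-5p.

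Other microRNAs whose ODD and EVEN libraries did not overlap were named by size and did not pass. Chance alone gives such a separation to 10% of microRNAs with 3 against 3. Higher with ODD probes in all libraries were miR-141-3p (6 reads against 0), miR-3135b, miR-4492 (928 ± 58 against 527 ± 458 RPM), miR-186-5p (801 ± 191 against 396 ± 170 RPM), miR-130a-3p, miR-24-3p, miR-1273g-3p and miR-1246 (6432 ± 998 against 4863 ± 686 RPM; SD, n = 3 each). Lower in all libraries were miR-6756-3p, miR-7706, miR-5095, miR-671-3p (283 ± 183 against 749 ± 264 RPM) and miR-146b-5p (579 ± 145 against 1063 ± 367 RPM; SD, n = 3 each).

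No list shifted between ODD and EVEN probes by camera, with adjusted p from 0.577 to 0.805 at the preset correlation. In the let-7 family 1 of 9 members fell over all microRNAs and 2 passed adjusted over the list alone, let-7f-5p and let-7c-5p. let-7c-5p, named after its values were seen, had 2352 ± 2892 RPM with ODD and 432 ± 390 RPM with EVEN probes (SD, n = 3 each), with 23 reads in ODD replicate 3 and 0 in EVEN replicate 3. Of the epithelial markers, miR-141-3p passed adjusted over the list alone (adjusted p = 0.0352 by limma, 2 tested) but not over all microRNAs (adjusted p = 0.909 by limma). It had 2 reads in each ODD library and 0 in each EVEN library, so its difference follows the pseudocount and rests on 6 reads. No member of the remaining lists passed in either way.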

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

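The simulations, the test of summed let-7 reads, both depth tests and the test of description numbers were chosen after the result was seen. The counts over other splits were set up before their results were seen.

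let-7f-5p differed between the probe sets, with a log2 difference between the ODD and EVEN effects of -1.16 by limma. Against the scrambled library the log2 difference was 0.20 with ODD probes and 1.36 with EVEN probes (limma, adjusted p = 0.798 and 0.0692). The tables argue against a trend with library depth as the whole cause, since with log2 depth in the fit the difference was -1.29 (95% interval -1.76 to -0.83, adjusted p = 0.00243 by limma). Reads passed between let-7f-5p and the near-identical let-7a-5p could also give the pattern. The summed RPM of both differed by -0.18 on the log2 scale (95% interval -0.60 to 0.24), which holds both 0 and the -0.28 that an unmoved let-7a-5p would give, so this cannot be told apart from a true difference. The real split of the 6 libraries gave 1 call and the highest other 0, and 1 of 10 splits gave as many, too few splits for a share under 0.05; a difference in what the probe sets capture stays open and untested.

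miR-184 and miR-17-5p had reads in 6 of 6 X1-probe libraries each, above the scrambled floor in 4 and 3 of them. Sampling of few reads in the scrambled library could account for both, since 84 of 100 simulations with no difference gave at least 2 higher calls, with up to 12. The simulations held no spread between captures beyond counting error, so their share need not be the rate for these libraries. In the data 11 microRNAs had 0 scrambled reads and reads in all 6 X1-probe libraries, against 9.21 simulated (95% range 4 to 15). With each library in turn as the lone control, the scrambled library gave 2 calls, and 2 of 7 choices gave as many; the highest other was EVEN replicate 3 with 7, while the shallower ODD replicate 3 gave 1, and 7 choices are too few for a share under 0.05. Binding of these microRNAs to the BRAF-X1 mRNA stays open and was not tested apart from sampling.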

How the results depend on the processing

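Pseudocount 250, the mean of at least 1000 RPM, all hairpin rows and the fit without replicate 3 of ODD and EVEN were chosen after seeing the data.

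The 2 higher calls with X1 probes fell to 1 under quantile scaling and to 0 under pseudocount 250 and under a mean of at least 1000 RPM, which removes both microRNAs. The count rose to 3 with no filter and without the eBayes trend, both times with miR-98-5p, and without EVEN replicate 3, with miR-3605-3p, named after its values were seen. With ODD and EVEN replicate 3 alone, which carry the scrambled library's number, the log2 differences were 7.02 for miR-184 and 6.48 for miR-17-5p. That setting took its spread from the fit to all 7 libraries. Lower calls went from 0 to 9 with no filter. The count higher with both probe sets was 0 under quantile scaling, without the eBayes trend, under pseudocount 250 and under a mean of at least 1000 RPM. miR-184 passed in 15 of 17 settings and miR-17-5p in 14 of 17. The ODD and EVEN count of 1 went to 0 under pseudocount 1, no filter, the 100 RPM filter, median-of-ratios and quantile scaling, to 3 without the trend (miR-153-3p, miR-194-5p and miR-6756-3p, named after their values were seen), and to 2 with all hairpin rows, both of them let-7f-5p. It ranged from 0 to 3 over the left-out libraries and was 1 without replicate 3 of both sets. Under quantile scaling 2 lists passed for X1 probes, let-7 and miR-17-92 (adjusted p = 0.0396 each by camera, 0.536 and 0.484 with an estimated correlation). With ODD and EVEN probes the top 10 held 56.4% and 58.0% of the tested RPM, which omits repeated hairpin rows. The top 20 held 53.3% and 54.3% of the whole RPM total. The causes of change were not tested, except where microRNAs or rows were left out or added.

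With the replicate block, the description number, the counts were 0 higher with X1 probes, 0 with both sets and 0 between ODD and EVEN. The adjusted p by limma was then 0.111 for miR-184 and miR-17-5p and 0.0559 for let-7f-5p. Same-number libraries' deviations correlated at -0.044, 0.072 and 0.019 across microRNAs. Pairing stays open, as most had few reads and same-number distances were lower (0.130 against 0.155). Signs that turned were those of miR-181a-5p (-0.084 with the block and with number 12 alone, and -0.033 to 0.15 over the left-out libraries), miR-191-5p (0.018) and miR-423-5p (0.015) with the block and with number 12 alone, and miR-27b-3p (0.027 under quantile scaling). In 30 named microRNAs of X1 against scrambled 501 of 517 values kept direction and call, in 14 of ODD against EVEN 219 of 232. Most were non-calls named for same-side libraries. The median log2 difference of all microRNAs, 0.096, was 0.50 with no filter, -0.095 with the 100 RPM filter and 0 with the block. The edgeR and seed-site alternatives were not run. Depth limits all of this, since the floor of 3 reads is worth 646 RPM in the scrambled library.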

Other observations

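The tests of description numbers and of depth below were chosen after the result was seen.

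The scrambled library was no farther from the X1-probe libraries than these were from one another. Its mean Bray-Curtis distance to the other 6 libraries was 0.148, rank 4 of 7 from the highest, where sampling alone gives 0.0981. Its nearest libraries were EVEN replicate 3 (0.113) and ODD replicate 3 (0.129), which carry its number 12, and it lay 0.162 on average from the replicates 1 and 2. Libraries of the same number could be alike: the mean distance over the 5 same-number pairs was 0.130 against 0.155 over the 16 others (exact one-sided permutation p = 0.00952 over 210 assignments), and among the X1-probe libraries alone the same-number pairing had the lowest mean of 15 (exact p = 0.0667, the smallest possible). All 3 of the shallowest libraries carry number 12, so depth and description number cannot be told apart for the scrambled library. MicroRNAs that come down with any probe stay open as well, since no unselected RNA was analysed here.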
